A study of Arabidopsis thaliana with 24 samples.

How the data were processed

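RNA of Arabidopsis inflorescences was compared on 24 Agilent arrays with 2 colours each. The plants carried LFY-GR, the floral regulator LEAFY (LFY) fused to the hormone-binding part of the glucocorticoid receptor, which is held out of the nucleus until dexamethasone (DEX) is given. On every array one dye carried RNA of DEX-treated plants and the other RNA of mock-treated plants. The time course had 20 arrays, 4 replicates (numbered 1, 2, 4 and 5) at each of 0, 2, 4, 8 and 12 h. The second experiment had 4 arrays taken at 3 h with the protein synthesis inhibitor cycloheximide on both sides. Each replicate pooled about 20 to 25 plants of about 4 weeks. DEX was in Cy3 in replicates 1 and 5 of the time course and in Cy5 in replicates 2 and 4. With cycloheximide, DEX was in Cy5 in replicates 1 and 3 and in Cy3 in replicates 2 and 4.

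The sample title and the time given among the sample's characteristics differed on 10 arrays, all of time course replicates 2 and 4. The title was used, and the other reading was run as an alternative. The series design describes LFY-GR lines in both experiments, while the treatment text also mentions an inducible AP1-GR line in plants mutant for ap1 and cal. The plants are described here as in the series design. If any array held such plants instead, its AP1 and CAL values would not speak of the normal genes, and no value here settles this.

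Spot brightness was in units of intensity, per the file headers, as median pixel signal and median local background in each channel, with no normalization. The same files held processed signals, also intensity, from which the background had been subtracted and which the scanner software had normalized between dyes. The deposited series table held log10 ratios of Cy5 over Cy3 processed signal. These were identical to the log ratios of the scanner files, so that scale, centring and direction were settled; the column medians lay between 0 and 0.00318. The file headers named Agilent Feature Extraction 10.5.1.1, and the submitters' processing notes named version 9.5.3.1.

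The files held no mean signal, so the median signals were corrected by normexp with an offset of 50, which took the place of the mean signals planned. Loess was then applied within each array, with weight 0 for control spots, and ratios were turned to log2(DEX/mock). Of 45210 spots per array, 1417 were controls. Non-uniform and population outlier spots were left out, 8 to 598 per array in the time course and 12 to 819 with cycloheximide. No coordinates are given, since the array's build and the reference table's (TAIR10.1) differ; the table served for names and neighbours, and 23804 of the 24129 genes kept matched it.

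A probe was kept where it lay well above background on at least 2 arrays of a treatment and time group. Of 43643 probes, 36953 named a locus. A gene was represented by its brightest probe, and 4164 genes had several. Among called genes with several probes, another probe had the opposite sign for 29 of 405 at 2 h, 53 of 734 at 4 h, 47 of 547 at 8 h, 74 of 762 at 12 h and 2 of 36 with cycloheximide.

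The 20 time course arrays were fitted together in limma 3.58.1 under R 4.3.3 (data.table, version 1.17.8, read the files), with a mean per time point and a gene-wise dye term, and each mean was tested against 0. The test was two-sided, from moderated statistics, and a call needed a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. A moderated F test asked whether the ratio differed among the 5 times. The 4 cycloheximide arrays were fitted alone with a dye term, and a fit of all 24 arrays compared 3 h with cycloheximide with the mean of 2 h and 4 h. The fits held 23870, 24128 and 23862 genes. Overlaps of calls were tested by a two-sided Fisher exact test over genes. Errors printed with log2 ratios are standard errors of the fit (SE), with n = 4 arrays per group unless stated. Precision is limited by the number of arrays.

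There were 13 gene lists: floral meristem identity and known LFY targets; floral organ identity; flowering time and inflorescence identity; meristem, boundary and organ polarity; gibberellin; auxin; cytokinin; biotic defence; abiotic stress, touch and jasmonate; circadian clock; cell cycle; and, as markers of other tissue, photosynthesis and anther and pollen. Several genes stand in more than one list, among them AP1, AP3, PI, AG, SEP3, SEP4, TFL1, FD, RAX1 and ELA1. Each list was tested by limma's camera in its pre-ranked form on the moderated statistics, against all other genes, with a preset correlation of 0.01 and again with the correlation estimated from the residuals. The p-values were adjusted over all lists and comparisons. The genes named are, per comparison, the 10 with the largest rise and the 10 with the largest fall among those called with the same sign on all 4 arrays, every member of both floral lists, and from each other list up to 4 members with the smallest adjusted p. The text gives values for only a part of these genes, and 1 of them is left out of it on purpose and not reported here. Design, lists, rule and alternatives were fixed before the data were examined, except for 3 alternatives added later and named where they are reported, the median signals, and the pre-ranked form of camera, which took the place of camera itself because of the dye term and missing spots.

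On simulated ratios for 22620 genes, recovery at 2 h was 98% of 1.5-fold and 99% of 2-fold changes when the spread of each gene was the moderated one, and 96% and 99% with the raw spread. With cycloheximide it was 95% and 100% with the moderated spread but 29% and 65% with the raw one, so the sensitivity of that experiment is uncertain. The moderated spread was adopted after the raw one had been run. The simulated noise was independent between genes and arrays. Structure shared by the genes of an array was not simulated, so these recoveries may be too high. In the comparison of both experiments, 135 of 282 simulated calls (moderated) or 317 of 465 (raw) were genes without a change. The median residual SD was 0.102 in the time course and 0.149 with cycloheximide. A test that gives each experiment its own spread was added, with 16 of 112 and 63 of 153 such calls.

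The alternatives were the time from the characteristics, replicates 1 and 5 alone, Agilent's processed signals, the series table, median centring without loess, Aquantile after loess, no filter and a stricter filter, the mean over probes, no dye term, each time fitted alone, the replicate number or the slide as a block, array weights, a mean-variance trend, and leaving out each replicate. Replicates 1 and 5 both had DEX in Cy3, so their fit alone had no dye term. Median centring alone left the median of all genes at -0.19 at 0 h, 0.45 at 2 h, 0.17 at 4 h, -0.12 at 12 h and 0.16 with cycloheximide, against values between -0.01 and 0.03 with loess. All log2 ratios are therefore relative to the loess curve of each array. The 24 arrays came from 7 slides and 5 scan days. Apart from 0 h, each time course slide held 1 replicate, the 4 cycloheximide arrays shared a slide, and DEX and mock shared every array. Probes that name no locus were tested separately and are reported with the additional observations.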

Results

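DEX and mock RNA from inflorescences of LFY-GR plants were hybridized together on 24 arrays, in 6 groups of 4. LFY turns meristems on the flank of the inflorescence into flowers, and the series concerns its interplay with AP1 and CAL, a pair of related MADS-box regulators with overlapping roles in this step. Of the groups, 5 formed a time course over 0, 2, 4, 8 and 12 h after treatment. The other was taken at 3 h with cycloheximide, where RNA changes that need newly made protein should be missing. In the time course 56.6% to 64.9% of spots were well above background per array and channel, with median signals of 49 to 72.5 in Cy3 and 87 to 124 in Cy5. With cycloheximide the range was 49.3% to 86.9%, with medians of 62 to 230 in Cy3 and 114 to 364 in Cy5, the highest on the array of replicate 2.

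At 0 h, the background for the later times, the floral regulators lay near equality. The log2 ratio was -0.10 ± 0.10 for AP1, -0.14 ± 0.10 for CAL, -0.12 ± 0.14 for TFL1 and -0.01 ± 0.15 for UFO. LFY itself had 0.26 ± 0.14 and passed the test at no time; whether its probe also reads the RNA of LFY-GR is not known from the files. limma called 0 of 23870 genes, with 574 at an unadjusted p under 0.05, and 0 of 13 lists passed. With array weights 1829 genes were called at 0 h. Between arrays of 0 h the correlation across genes ran from -0.38 to 0.64, and genes are not independent replicates. Its sign went with the dye orientation. Pairs with DEX in the same dye had 0.64 and 0.08, and every pair with DEX in opposite dyes was negative (-0.38 to -0.2).

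At 2 h after DEX the floral regulators AP1 and CAL were already higher than in mock tissue, AP1 1.59-fold (0.67 ± 0.10) and CAL by 0.43 ± 0.10 on the log2 scale. RAX1, a MYB gene of axillary meristems, rose 2.36-fold (1.24 ± 0.13), the cytochrome P450 gene ELA1 2.52-fold (1.34 ± 0.15) and the homeobox gene LMI1 1.97-fold (0.98 ± 0.09). TFL1, which keeps the shoot meristem from turning into a flower, rose as well, 2.33-fold (1.22 ± 0.14), and FD, a bZIP partner of the flowering signal FT, by 0.71 ± 0.07. UFO, an F-box cofactor of LFY, fell by 0.97 ± 0.15. SEP3 reached 0.81 ± 0.21 and PI 0.41 ± 0.08, the latter higher on 3 of 4 arrays, while AG at 0.50 ± 0.24 and AP3 at 0.48 ± 0.28 did not pass. The call was lost for CAL without replicate 2 or 4 (0.46 and 0.34), for SEP3 without replicate 2, 4 or 5 (0.70, 0.95 and 0.55) and for PI without replicate 4 (0.39). The treatment text also names plants mutant for ap1 and cal, and if any array held such plants, its AP1 and CAL values would not be those of the normal genes.

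Outside the floral genes, the largest rises at 2 h were AT5G60630 at 2.41 ± 0.12 (adjusted p = 1.9e-08) and AT3G13662 at 2.05 ± 0.20. They were followed by the gibberellin biosynthesis gene GA20OX1 at 1.93 ± 0.15 and the basic helix-loop-helix gene AIF1 at 1.88 ± 0.14. The gibberellin catabolism gene GA2OX2 rose by 1.62 ± 0.19, and the asparagine synthetase gene ASN1 by 1.62 ± 0.35. The value of ASN1 at 2 h was 0.98 without replicate 5, whose array had 3.61, and its call was lost without replicate 2 (1.81, adjusted p = 0.062). The largest fall was that of the homeobox gene WOX4, with -1.43 ± 0.20 (adjusted p = 0.00032), before the gene listed as RING (AT4G19700) with -1.32 ± 0.10, AT4G16447 with -1.25 ± 0.08 and AT3G50230 with -1.08 ± 0.13. In the floral meristem list 12 of 21 measured members rose and 1 fell (14 and 2 adjusted over the list alone), and the list moved up against other genes (adjusted p = 5.4e-08, and adjusted p = 4e-04 with an estimated correlation). In the floral organ list 4 of 13 rose and 1 fell (5 and 1 adjusted over the list alone), the fall being AP2 with -0.49 ± 0.06. That list's adjusted p of 0.035 was not kept, with adjusted p = 0.51 with an estimated correlation, and was 0.093 without replicate 4 and 0.4 without replicate 5. In the meristem, boundary and organ polarity list 5 of 29 rose and 8 fell (5 and 16 adjusted over the list alone), and the list moved down (adjusted p = 5.3e-06, and adjusted p = 0.0048 with an estimated correlation). The boundary gene CUC1 had -0.58 ± 0.05 and the leaf polarity gene REV -0.47 ± 0.04, while the stem cell regulator WUS rose by 0.41 ± 0.05. With median centring alone, AP2, CUC1, REV and the median of this meristem list were above 0, at 0.12, 0.07, 0.16 and 0.38, where the median of all genes was 0.45, and the list's call was lost (adjusted p = 0.4). DRN fell by 0.68 ± 0.07 and the gibberellin repressor gene RGL1 by 0.66 ± 0.09, and the cyclin gene CYCD3;1 rose by 0.68 ± 0.06.

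Altogether 1292 genes changed at 2 h, 594 higher and 698 lower, 74 and 124 of them by at least 1.5-fold. The share of falls was 54%, against 69.9% with Agilent's processed signals and 2.44% with median centring alone (40 higher, 1 lower). The balance also changed with the replicates, to 324 higher and 900 lower without replicate 1 and 460 and 351 without replicate 4. Neither direction can therefore be said to prevail. Replicates 1 and 5 alone gave 905 higher and 331 lower. Both had DEX in Cy3 and were fitted without a dye term, so dye effects cannot be told apart from DEX there. Median centring alone called 41 genes, no dye term 803 and the 4 arrays fitted alone 174, and leaving out replicate 2, 4 or 5 gave 632, 811 or 590.

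At 4 h TFL1 had risen 3.83-fold (1.94 ± 0.14) and LMI1 by 1.57 ± 0.09, while AP1 at 0.52 ± 0.10 and CAL at 0.46 ± 0.10 were still called. RAX1 was at 1.26 ± 0.13, ELA1 at 1.37 ± 0.15, SEP3 at 1.01 ± 0.21 and PI at 0.43 ± 0.08. BOP1 and BOP2, which act in leaf and floral patterning, rose by 0.25 ± 0.06 and 0.34 ± 0.09, but BOP1 was not called without replicate 1 or 2 (0.22 and 0.25), nor BOP2 without replicate 1, 4 or 5 (0.37, 0.37 and 0.29). UFO had fallen by 0.92 ± 0.15 and PUCHI, an AP2/ERF gene of floral meristems, by 0.55 ± 0.12 (-0.43 and not called without replicate 4). In the floral meristem list 13 of 21 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 2.1e-08, and adjusted p = 0.00027 with an estimated correlation).

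AT5G60630 again had the largest rise (2.78 ± 0.12), with GA20OX1 at 2.39 ± 0.15, TBL38 at 2.16 ± 0.17, AIF1 at 1.99 ± 0.14 and the proline synthesis gene P5CS1 at 1.73 ± 0.15. The largest falls were CYP91A2 with -1.64 ± 0.11, WOX4 with -1.48 ± 0.20 and FAF2 with -1.45 ± 0.29 (-1.17 and not called without replicate 4). In the meristem, boundary and organ polarity list 7 of 29 rose and 14 fell (7 and 18 adjusted over the list alone). KNAT1, a homeobox gene of the shoot meristem, fell by 1.37 ± 0.09, CLV1, a receptor kinase gene that restricts stem cells, by 0.83 ± 0.07 and CUC1 by 0.75 ± 0.05, while WUS rose by 0.57 ± 0.05. The list's call (adjusted p = 0.0055) was lost with adjusted p = 0.15 with an estimated correlation, and its median of -0.19 was 0.06 with median centring alone (adjusted p = 0.88), where the median of all genes was 0.17. The auxin biosynthesis gene YUC4 rose by 1.01 ± 0.10, the kinase gene WAG2 by 0.96 ± 0.11 and the auxin response gene IAA1 by 0.62 ± 0.07. The flowering repressor TEM1 rose by 1.31 ± 0.16 and TOE3 fell by 0.64 ± 0.08.

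In total 2947 genes changed at 4 h, 1281 higher and 1666 lower, 120 and 404 of them by at least 1.5-fold. The 2 h and 4 h calls shared 374 higher genes, where 31.9 would be shared by independent lists, and 579 lower genes, where 48.7 would be. Both times share a fit and each gene's estimated spread, so their lists are not independent and tend to overlap for that reason too. Falls made up 56.5% of the calls, against 43.8% with Agilent's processed signals and 24.1% with median centring alone (41 higher, 13 lower), and without replicate 2 the calls were 812 higher and 1785 lower. Median centring alone called 54 genes and the 4 arrays fitted alone 1607, and leaving out replicate 1 or 4 gave 1939 or 1477.

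**Figure D1:**
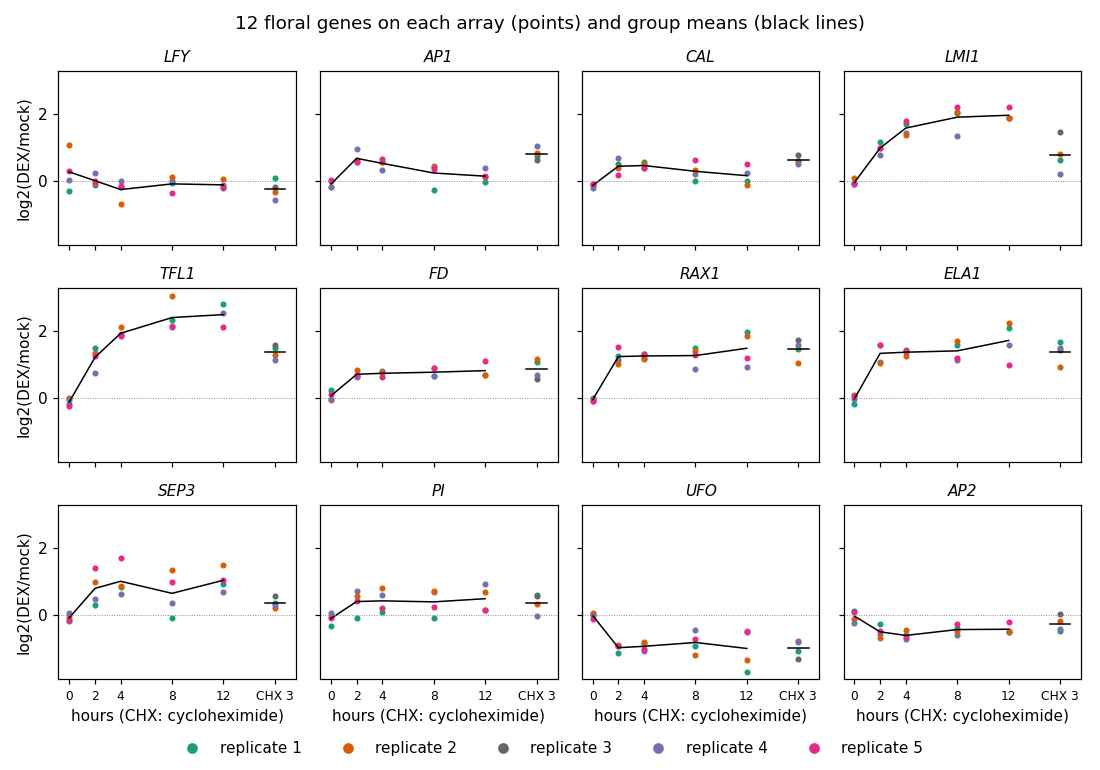
Log2(DEX/mock) of 12 floral genes (vertical axis) against hours after treatment, with the cycloheximide group (CHX, 3 h) set apart at the right of each panel. Points are single arrays coloured by replicate and black lines are group means; TFL1 and LMI1 climb to 2.51 and 1.96 at 12 h, whereas AP1 is at 0.67 at 2 h and 0.14 at 12 h.

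At 8 h AP1 was back at 0.23 ± 0.10 and CAL at 0.28 ± 0.10, neither of which passed the test. TFL1 was 5.29-fold higher than in mock tissue (2.40 ± 0.14) and LMI1 had a log2 ratio of 1.90 ± 0.09 (adjusted p = 2.2e-09). RAX1 at 1.27 ± 0.13, ELA1 at 1.41 ± 0.15, FD at 0.77 ± 0.07 and MYB17 at 0.40 ± 0.05 stayed higher, and UFO was at -0.81 ± 0.15. SEP3 at 0.66 ± 0.21 did not pass. In the floral meristem list 9 of 21 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 1.5e-08, and adjusted p = 0.00023 with an estimated correlation).

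In the auxin list 9 of 19 rose and 3 fell at 8 h (10 and 4 adjusted over the list alone), and the list moved up (adjusted p = 1.2e-06, and adjusted p = 0.012 with an estimated correlation). YUC4 rose by 1.04 ± 0.10, WAG2 by 0.98 ± 0.11, IAA1 by 0.65 ± 0.07 and MP, an auxin response factor needed for flower initiation, by 0.41 ± 0.04. KNAT1 fell by 1.29 ± 0.09 and CUC1 by 0.57 ± 0.05, while FIL and ATH1 rose by 0.45 ± 0.04 and 0.61 ± 0.04. The rises at 8 h were led by AT5G60630 at 2.83 ± 0.12, GA20OX1 at 2.56 ± 0.15 and the flavonol synthase gene FLS6 at 2.43 ± 0.23. AT4G21630 had the largest fall with -1.74 ± 0.17, and its neighbours AT4G21640 and AT4G21650 had -1.63 ± 0.16 and -1.50 ± 0.15. Whether the probes of these adjacent genes read each other's RNA is unknown. FAF3 fell by 1.63 ± 0.34 and FAF2 by 1.42 ± 0.29, but FAF3 was not called without replicate 1 or 5 (-1.64 and -1.53), nor FAF2 without replicate 4 (-1.21).

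The test called 2030 genes at 8 h, 584 higher and 1446 lower, 126 and 361 of them by at least 1.5-fold. Falls were 71.2% of the calls, against 51.1% with Agilent's processed signals and 46.7% of the 30 genes called with median centring alone. With the time from the characteristics 0 genes were called, with replicates 1 and 5 alone 1324, and with the 4 arrays fitted alone 829.

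At 12 h TFL1 was 5.69-fold higher than in mock tissue (2.51 ± 0.16, n = 3 arrays) and LMI1 3.88-fold (1.96 ± 0.09), and AP1 at 0.14 ± 0.10 and CAL at 0.15 ± 0.10 did not pass. RAX1 rose by 1.49 ± 0.13, ELA1 by 1.72 ± 0.15 and SEP3 by 1.05 ± 0.21. UFO fell by 0.99 ± 0.15 and PUCHI by 0.65 ± 0.12. FUL, a relative of AP1, was called with -0.17 ± 0.05 although it was not below 0 on every array, and the call was lost without replicate 1, 2 or 5 (-0.18, -0.13 and -0.18). In the floral meristem list 11 of 21 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 1.5e-07, and adjusted p = 0.00053 with an estimated correlation).

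SWEET10, a sugar transporter gene, had the largest fall at 12 h with -2.01 ± 0.19, a 4.04-fold difference, followed by FAF3 with -1.95 ± 0.34 and AT4G21630 with -1.81 ± 0.17. FAF3 at 12 h owed its rank to replicate 4 (-4.08 on that array) and was at -1.25 without it, still called. FLS6 at 2.75 ± 0.23 and GA20OX1 at 2.71 ± 0.15 had the largest rises. SPL3, a promoter of flowering, fell by 0.91 ± 0.10 and KNAT1 by 1.52 ± 0.09, while TEM1 rose by 1.41 ± 0.16 and GA2OX2 by 1.94 ± 0.19. In the auxin list 10 of 19 rose and 4 fell (10 and 5 adjusted over the list alone), with YUC4 at 1.19 ± 0.10 and MP at 0.48 ± 0.04. The list's adjusted p of 0.00015 compared with adjusted p = 0.085 with an estimated correlation. In the biotic defence list 4 of 15 rose and 1 fell (4 and 2 adjusted over the list alone), PR2 by 0.49 ± 0.13 and FRK1 by 0.40 ± 0.11, PR2 not called without replicate 1 or 4 (0.36 and 0.46) and FRK1 not without replicate 1, 2 or 4 (0.23, 0.42 and 0.47). The list's median of 0.14 was -0.05 with median centring alone, where the median of all genes was -0.12. The call (adjusted p = 0.026) was lost with adjusted p = 0.43 with an estimated correlation, and without replicate 1 (adjusted p = 0.069). PDF1.2 of this list, called with 0.77 ± 0.16, was well above background on 1 of 4 mock arrays and was not called without replicate 5 (0.60).

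The 12 h calls came to 3038 genes, 986 higher and 2052 lower, 158 and 461 of them by at least 1.5-fold. They shared 446 higher genes with 8 h (24.1 for independent lists) and 1261 lower genes (124), though lists from a shared fit are not independent. Falls were 67.5% of the calls, against 40.9% with Agilent's processed signals and 56.6% of the 53 genes called with median centring alone. The time from the characteristics gave 0 genes, replicates 1 and 5 alone 1765 and the 4 arrays fitted alone 1312, and leaving out replicate 1 or 4 gave 1944 or 1815.

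**Figure D2:**
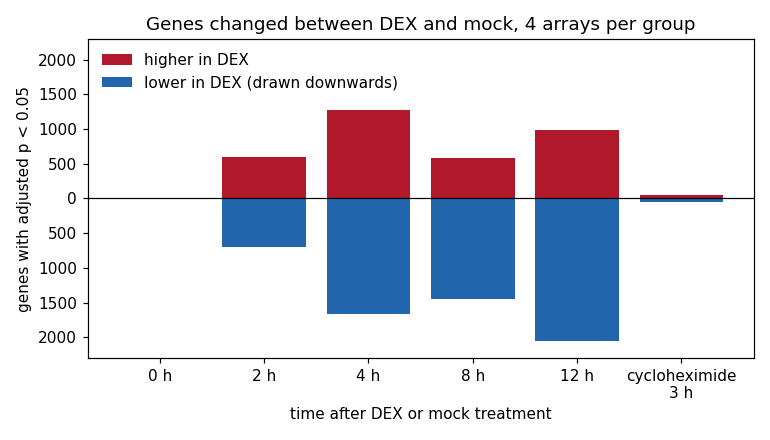
Number of genes with an adjusted p under 0.05 in each group of 4 arrays (vertical axis) against time after treatment (horizontal axis), with genes higher in DEX drawn upwards and genes lower in DEX downwards. The counts go from 0 at 0 h to 3038 at 12 h. The split between rises and falls depends on the normalization and, at 2 h and 4 h, also on the replicates.

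The response of several floral genes differed among the 5 times. AP1 differed with time (F test, adjusted p = 0.011), as did TFL1 (adjusted p = 1.08e-05) and LMI1 (adjusted p = 8.19e-07), while CAL did not pass (adjusted p = 0.0616). SPL3 (adjusted p = 0.00166) went from -0.03 ± 0.10 at 2 h to -0.91 ± 0.10 at 12 h, and MP (adjusted p = 0.000238) from 0.06 ± 0.04 to 0.48 ± 0.04. REV (adjusted p = 0.000657) went the other way, from -0.47 ± 0.04 at 2 h to -0.15 ± 0.04 at 12 h. Over the 5 times 917 genes differed. From 2 to 12 h, 184 genes were called higher at all 4 times and 452 lower at all 4, out of 4733 called at one or more, and 17 were higher at one time and lower at another. Since the 0 h arrays lay on slides of their own, an F test over 2 to 12 h with the slide as a block was added after seeing the data; it called 90 genes, TFL1, LMI1, SPL3 and MP among them but not AP1, CAL or REV. The count of 917 fell to 0 with the time from the characteristics and with median centring alone and to 111 with replicates 1 and 5, and leaving out replicate 1, 2, 4 or 5 gave 358, 598, 507 or 417.

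With cycloheximide, AP1 rose 1.76-fold (0.81 ± 0.07, adjusted p = 0.028) and CAL by 0.61 ± 0.07 (adjusted p = 0.046), both on 4 of 4 arrays. RAX1 rose 2.75-fold (1.46 ± 0.11), TFL1 2.6-fold (1.38 ± 0.07) and ELA1 by 1.39 ± 0.11, and UFO fell by 0.99 ± 0.07. AIF1 rose 6.23-fold (2.64 ± 0.11, adjusted p = 0.013), and AT3G13662 by 3.19 ± 0.22, AT5G60630 by 2.38 ± 0.14, AT5G03890 by 2.03 ± 0.10 and GA20OX1 by 1.91 ± 0.13. The largest falls were AT3G28560 with -1.27 ± 0.08, AT1G21050 with -1.27 ± 0.12 and FAF2 with -1.27 ± 0.09. LMI1 at 0.76 ± 0.17, FD at 0.87 ± 0.12 and SEP3 at 0.37 ± 0.07 were not called (adjusted p = 0.16, 0.071 and 0.12). Many calls were lost when an array was left out. Of the 31 named genes called, 29, 3, 31 and 22 lost the call without replicate 1, 2, 3 or 4, and 0 changed direction. With an array left out, the spread is estimated from less. A lost call therefore need not mean that a single array carried the change. AP1 was at 0.78, 0.84 and 0.76 without replicate 1, 3 or 4 and CAL at 0.65, 0.58, 0.56 and 0.63 without replicate 1, 2, 3 or 4, none of them called. TFL1 was not called without replicate 1 or 3 (1.41 and 1.35), nor RAX1 (1.53 and 1.39), and AIF1 not without replicate 3 (2.52).

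Hormone genes called with cycloheximide included YUC4 at 1.00 ± 0.07, IAA3 at 0.64 ± 0.07, GA2OX2 at 1.22 ± 0.13 and RGL1 at -0.69 ± 0.07. Without replicate 1, 3 or 4 none of these was called, with YUC4 at 1.06, 0.94 and 0.97, IAA3 at 0.61, 0.67 and 0.59, GA2OX2 at 1.21, 1.23 and 1.03 and RGL1 at -0.72, -0.65 and -0.63, and without replicate 2 IAA3 was not called either (0.69). In the floral meristem list 5 of 21 rose and 1 fell (13 and 3 adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 5.7e-07 with an estimated correlation). In the meristem, boundary and organ polarity list 1 of 29 rose, RAX1, and 1 fell, AS1 with -0.56 ± 0.07 (4 and 8 adjusted over the list alone). AS1 was not called without replicate 1, 2, 3 or 4 (-0.56, -0.60, -0.56 and -0.52). That list moved down (adjusted p = 0.0022, and adjusted p = 0.00053 with an estimated correlation), with a median of -0.12. With median centring alone its median was 0.08, where that of all genes was 0.16, and the call was lost (adjusted p = 0.88). In the auxin list 2 of 19 rose and 1 fell (2 and 2 adjusted over the list alone); the list moved down with a median of -0.17 (adjusted p = 0.018, but adjusted p = 0.51 with an estimated correlation), a median of 0.07 with median centring alone (adjusted p = 0.79), again beside 0.16 for all genes. Without replicate 1 or 4 the auxin call was lost as well (adjusted p = 0.15 and 0.078). In the circadian clock list 1 of 11 rose (6 and 0 adjusted over the list alone), the morning gene CCA1 by 0.79 ± 0.09 (0.73, 0.85 and 0.70 and not called without replicate 1, 3 or 4), and the list's adjusted p of 1.3e-05 was lost with adjusted p = 0.17 with an estimated correlation. In the abiotic stress list 0 of 17 members passed (5 higher and 1 lower adjusted over the list alone), and its upward adjusted p of 0.014 was lost with adjusted p = 0.22 with an estimated correlation and with adjusted p = 0.15 without replicate 4.

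In all 100 of 24128 genes changed with cycloheximide, 52 higher and 48 lower, with 2936 at an unadjusted p under 0.05. The count was 3 with Agilent's processed signals or the series table, 0 with median centring alone or a mean-variance trend, 43 without the filter, 498 with a stricter filter and 196 without the dye term. Leaving out replicate 1, 2, 3 or 4 gave 5, 186, 0 or 14, so the number of calls was not stable when an array was left out.

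Most genes called with cycloheximide were also called at 2 h or 4 h, the times on either side of 3 h. The overlap was taken at these times only, so it does not set them apart as early genes. Of the 52 higher genes, 46 were also higher at 2 h or 4 h, AP1, CAL, RAX1, TFL1 and GA20OX1 among them, where independent lists would share 3.3 (Fisher exact p = 4e-49). Of the 48 lower genes, 47 were also lower, UFO and FAF2 among them, where 3.6 would be shared (Fisher exact p = 3e-52). Both tests take genes read on the same arrays as independent, so their p-values do not measure replication over arrays. Of the 100 genes, 0 were called in the opposite direction at 2 h or 4 h. At 2 h 99 of the 100 genes had the same sign and at 4 h 97. Across all genes the Pearson correlation with cycloheximide was 0.643 at 2 h and 0.607 at 4 h. The 93 became 3 with Agilent's processed signals, 0 with median centring alone and 2, 156, 0 or 13 without cycloheximide replicate 1, 2, 3 or 4, following the number of calls.

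**Figure D3:**
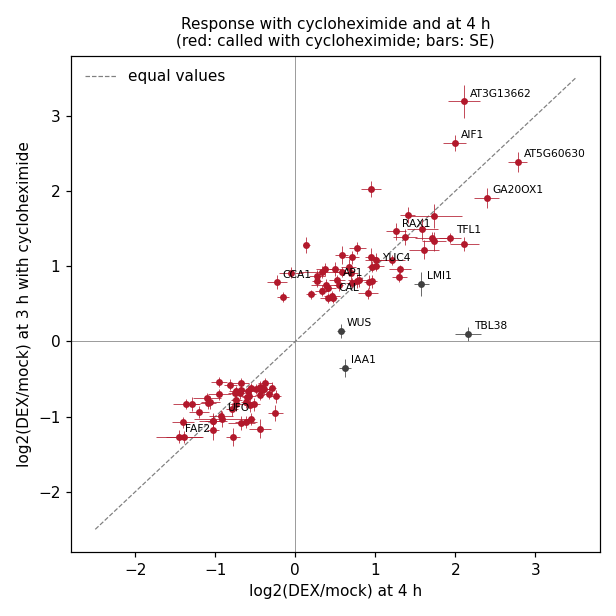
Log2(DEX/mock) at 3 h with cycloheximide (vertical axis) against log2(DEX/mock) at 4 h (horizontal axis) for the 100 genes called with cycloheximide (red) and TBL38, IAA1, WUS and LMI1 (grey), with SE bars and a dashed line of equal values. Of the 100 genes, 97 had the same sign at 4 h, while TBL38, at 2.16 at 4 h, lies far below the line.

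Some responses differed in size between the cycloheximide arrays and the mean of 2 h and 4 h. The cycloheximide arrays had a slide and a scan day of their own, and no array held 3 h without cycloheximide. An effect of cycloheximide therefore cannot be told apart from slide, scan day or experiment here. The log2 ratio with cycloheximide minus that mean was -1.59 for TBL38, -0.71 for IAA1 and -0.62 for SEP1, and 1.17 for AT5G03890 and 0.91 for CCA1. The floral genes AP1 (0.22 ± 0.12, adjusted p = 0.419), CAL (0.16 ± 0.11, adjusted p = 0.546), TFL1 (-0.20 ± 0.16, adjusted p = 0.604) and LMI1 (-0.51 ± 0.17, adjusted p = 0.17) were not shown to differ. The test called 176 genes, 109 higher with cycloheximide and 67 lower, and 38.1% were lower, against 54.5% of 101 with Agilent's processed signals. Since it made many false calls on simulated data, a test with each experiment's own spread was added after seeing the data. It called 23 genes, TBL38 (adjusted p = 1.3e-05), AT5G03890 (adjusted p = 0.0019), CCA1 (adjusted p = 0.0051) and SEP1 (adjusted p = 0.013) among them, but not IAA1 (adjusted p = 0.16). On simulated data 16 of its 112 calls (moderated spread) or 63 of 153 (raw spread) were false too. It recovered 10% or 29% of the smaller simulated differences, so a gene it did not call may still differ. For the test that called 176 genes, leaving out time course replicate 1, 2, 4 or 5 gave 50, 52, 64 or 54. Leaving out cycloheximide replicate 2, 3 or 4 gave 1025, 408 or 67. Without cycloheximide replicate 2 the balance turned, with 419 higher and 606 lower.

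Lists not named above did not pass at the preset correlation. In the flowering time list 4 of 25 rose and 3 fell at 2 h (4 and 8 adjusted over the list alone), with TEM1 at 1.18 ± 0.16 and FDP at 0.33 ± 0.06 (0.28 and not called without replicate 2), and 5 rose and 8 fell at 12 h (6 and 10 adjusted over the list alone). Its adjusted p lay between 0.056, at 0 h, and 0.98 over the 6 groups. At 2 h it was 0.067, and the list's median of -0.08 and mean of 0.05 differed in sign. In the gibberellin list 9 of 21 rose and 5 fell at 4 h (9 and 8 adjusted over the list alone), with a list adjusted p from 0.13 to 0.57 over the groups, although GA20OX1 and GA2OX2 stood among the largest rises. The auxin list had 8 rises and 5 falls among 19 genes at 4 h (9 and 5 adjusted over the list alone) and an adjusted p of 0.051. In the cytokinin list 2 of 11 fell at 12 h (1 higher and 3 lower adjusted over the list alone), AHK4 and ARR16, both with -0.22 but neither called without replicate 1, 2 or 4 (-0.22, -0.22 and -0.15 for AHK4, and -0.09, -0.22 and -0.25 for ARR16), and the list's adjusted p ran from 0.097 to 0.8. In the cell cycle list 1 of 6 rose at 2 h, CYCD3;1 (1 and 0 adjusted over the list alone). The list's adjusted p ran from 0.058, at 0 h, to 0.95, and was 0.1 at 2 h. The markers of other tissue gave no list call. Among photosynthesis genes 1 of 12 rose at 2 h, LHCB3 by 0.21 ± 0.05, not called without replicate 2, 4 or 5 (0.20, 0.16 and 0.23; 2 and 0 adjusted over the list alone). At 4 h 2 rose (3 and 0 adjusted over the list alone), RBCS1B by 0.19 ± 0.06 and LHCA1 by 0.22 ± 0.07, the latter not on every array. RBCS1B was not called without replicate 2, 4 or 5 (0.22, 0.15 and 0.17), nor LHCA1 without replicate 1, 2, 4 or 5 (0.21, 0.16, 0.27 and 0.25), and the lowest list adjusted p was 0.051. Of the anther and pollen list 4 of 8 genes were measured, 0 changed in any group (0 adjusted over the list alone), and the lowest adjusted p was 0.38.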

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

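The test bounds for the time labels were set after the values were seen, and the F test over 2 to 12 h, the tests of the bright array and of the sampling time and the test with each experiment's own spread were also chosen after the result was seen; the other tests were set beforehand. On 10 arrays the title and the characteristics give different times. A response score was taken over the 100 genes called with cycloheximide. It was the mean log2 ratio of the 52 higher genes minus that of the 48 lower genes. The score is thus a distance between both sets, not a mean response per gene. It was 1.43 to 2.02 on the 2 to 12 h arrays of replicates 1 and 5 and at most -0.04 on their 0 h arrays. The arrays that only the characteristics place at 0 h scored 1.33 and 1.38, which argues against the characteristics, and those that only the titles place at 0 h scored at most -0.01, which is in line with the titles. With the bound first chosen, the lowest 2 to 12 h score of replicates 1 and 5 (1.43), the value of 1.33 would have decided nothing. The score was not used to order the times from 2 to 12 h, so errors among these stay open.

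Falls outnumbered rises at 8 h and 12 h. No single replicate accounts for this, since leaving out any one left at least 66.3% falls at both times. With median centring alone the lower share was 46.7% at 8 h and 56.6% at 12 h, and with Agilent's processed signals it was 51.1% at 8 h and 40.9% at 12 h. The excess may therefore come from the loess step, and a biological excess of falls was not tested apart from it.

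Genes that rose less or fell more with cycloheximide than at 2 h and 4 h included TBL38 (-1.59), IAA1 (-0.71), SEP1 (-0.62), AT4G29100 (-0.40), FDP (-0.35) and WUS (-0.35), by a test of the difference. Slide, scan day and experiment differed along with cycloheximide, so these sources cannot be told apart from it. Against the bright array of replicate 2 as the only source, 20.9% of the 67 genes had their lowest value on it. The upper 95% limit of 32.6% takes genes read on the same arrays as independent, so it is too narrow. Leaving this array out changed the count of differing genes from 176 to 1025, so it did affect which genes were called. The test first set, of the same genes without this array, was bound to favour them. Against the sampling time, a value between those of 2 h and 4 h can differ from their mean only where these lie apart. Of the 67 genes, 9% had both times at least 2 SE from the mean (upper 95% limit 18.5%, again with genes taken as independent). Of these 6 genes, TBL38 and IAA1 among them, 0% lay between both times, but they are few. All 67 genes lay below both times by over 2 SE of the difference (median distance 0.3). They were picked for lying below the mean. For genes with a small step from 2 h to 4 h this distance followed from the choice, so it decides nothing. The steps do not use the cycloheximide values. In most of the 67 genes they were too small for a steady course to give a difference as large as that measured. A need for new protein in late responses also stays open, as 53.6% of the 905 genes higher at 4 h and not called at 2 h lay below their 2 h value, against 63.4% of the 374 higher at both. With each experiment's own spread IAA1, AT4G29100, FDP and WUS were no longer called (adjusted p = 0.16, 0.21, 0.37 and 0.44). That test recovered 10% (moderated spread) or 29% (raw spread) of the smaller simulated differences. The lost calls therefore do not show that these genes responded alike.

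The same difference was positive for CCA1 (0.91) and AT5G03890 (1.17). The counts of differing genes were 917 over the 5 times, 90 from 2 to 12 h with slide as a block and 176 between experiments. Among 100 draws of the times over the 20 arrays, 1 gave as many genes as the real 917, the real one, with 2 in the highest other. This speaks against times that fell on the arrays at random. The draws mixed the 0 h arrays, which lay on slides of their own, with the later ones. They therefore cannot tell time from slide at 0 h, nor do they test change among 2 to 12 h. Among 100 draws over the 12 arrays of the comparison between experiments, 3 gave 176 or more, and the highest other gave 730, which could reflect a structure of these samples beyond the labels or the false calls of this contrast (135 of 282 on simulated data), and these were not told apart. Exchanging DEX and mock on the 4 arrays of a group makes 8 splits, too few for a share under 0.05. The real splits gave 0 genes at 0 h (all 8 gave as many), 1292 at 2 h (highest other 228), 2947 at 4 h (6), 2030 at 8 h (0) and 3038 at 12 h (4), each of the last 4 counts reached in 1 split. With cycloheximide 7 splits could be fitted, and 1 gave the real 100 genes, with 0 in the highest other.

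Single arrays far from the other 3 of their group were found by Dixon's test in 231 groups of gene values and 30 groups of array measures, where chance flags about 1 in 20. At 2 h these were ASN1 on replicate 5 (3.61), UFO on replicate 1 (-1.13) and GI on replicate 4 (0.97). At 4 h they were TBL38 on replicate 4 (2.76) and, on replicate 2, AT1G61930 (-0.65), TEM1 (0.93), CUC1 (-0.41) and CLV1 (-0.58). At 8 h CBF3 stood apart on replicate 2 (-1.49). At 12 h they were LMI1 (2.19), AT1G11700 (-0.99), AP2 (-0.19) and PR2 (-0.07) on replicate 5, FAF3 (-4.08) and AT5G44630 (-2.13) on replicate 4 and AT4G21630 on replicate 2 (-1.56). With cycloheximide they were AT5G03890 on replicate 3 (2.45) and ASN1 (0.84) and GA2OX2 (0.69) on replicate 2. Among array measures, the median Cy5 signal of 8 h replicate 2 was 88, the share of Cy3 spots above background on 8 h replicate 5 was 57.6%, and cycloheximide replicate 2 had 819 excluded spots.

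Probes that name no locus, which the comparisons of genes do not use, were called in part: 3 of 3754 changed at 2 h, 23 at 4 h, 14 at 8 h and 17 at 12 h, while limma called 0 at 0 h and 0 of 3760 with cycloheximide, with 14 and 175 at an unadjusted p under 0.05.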

How the results depend on the processing

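Of the alternatives, 3 were chosen after the result was seen: the F test over 2 to 12 h with slide as a block (90 genes against 917), the 12 h count without the 12 h array of replicate 2 (2248 against 3038), and each experiment's own spread (23 against 176). The time from the characteristics called 0 genes at 8 h, 0 at 12 h and 0 in the F test. Replicates 1 and 5 alone, without a dye term, gave 1324, 1765 and 111, with 21 for the comparison of both experiments. Median centring alone called 41 genes at 2 h, 54 at 4 h, 30 at 8 h, 53 at 12 h, 0 with cycloheximide, 0 by F, 1 between experiments and 0 shared. Fitting each time alone gave 174, 1607, 829 and 1312. Leaving out the dye term gave 803 at 2 h, 196 with cycloheximide, 539 by F, 83 between experiments and 163 shared. Array weights gave 1829 at 0 h, 3492 by F and 17 between experiments. For cycloheximide and for the genes it shared with 2 h or 4 h, the counts were 3 and 3 with Agilent's processed signals, 3 and 3 with the series table, 43 and 40 without the filter, 498 and 352 with the stricter filter and 0 and 0 with a mean-variance trend. Between experiments, processed signals gave 101, the stricter filter 95 and a slide block 110.

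Leaving out each replicate in turn gave 590 (without replicate 5) to 1224 genes at 2 h, 1477 (without replicate 4) to 2597 at 4 h, 1358 to 1531 at 8 h, 1815 (without replicate 4) to 2480 at 12 h, 0 (without replicate 3) to 186 (without replicate 2) with cycloheximide, 358 to 598 by F, 50 to 1025 (without cycloheximide replicate 2) between experiments and 0 to 156 shared. Whether the numbers pair the samples was not clear. Residual correlations within a number ran from -0.23 to 0.63, beside a median of 0 for different numbers and times. Of the 20 arrays, 10 correlated best with their own number. From 2 to 12 h the number and the slide coincide, so they cannot be told apart there. With the replicate number as a block (consensus correlation 0.073) 1238, 2887, 1979 and 2981 genes were called from 2 h to 12 h, and 1224, 2852, 1965 and 2939 of these were also called without it. Among named genes, 3561 values kept direction and call, 755 kept direction and lost the call, and 4 turned. AP2, REV and CUC1 at 2 h were at 0.12, 0.16 and 0.07 with median centring alone, and JAZ1 at 4 h was at 0.01 with the time from the characteristics. Among list tests 1381 kept their side, 76 passed in addition and 32 lost the call.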

Other observations

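The genes in this part were chosen after their values were seen; the test of neighbours was set beforehand. Among the 90 genes whose response differed from 2 to 12 h with slide as a block, some single genes are named here; no group of genes was tested. GH3.4, an auxin-conjugating enzyme gene, went from -0.05 ± 0.18 at 2 h to 1.53 ± 0.18 at 12 h (adjusted p = 0.018), and its relative BRU6 from -0.06 ± 0.11 to 1.04 ± 0.11 (adjusted p = 0.00131). The homeobox gene HAT2 went from 0.05 ± 0.08 to 0.98 ± 0.08 (adjusted p = 0.0125), and PTL, a trihelix gene of sepal and petal development, from -0.09 ± 0.06 to 0.46 ± 0.06 (adjusted p = 0.00862). IAA18 went from -0.32 to 0.02 and AUX1 from -0.29 to 0.09. LCR68 and LCR69, which encode small cysteine-rich proteins, went from -0.05 ± 0.10 and -0.02 ± 0.11 at 2 h to -1.24 ± 0.10 and -1.16 ± 0.11 at 12 h (adjusted p = 0.00363 and 0.0119). SWEET10 went from 0.13 ± 0.19 to -2.01 ± 0.19 (adjusted p = 0.0183).

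With cycloheximide the cold and dehydration genes ERD14 and CBF2 differed from the mean of 2 h and 4 h by 0.94 ± 0.15 and 0.82 ± 0.13 (adjusted p = 0.00535 and 0.00289), and ERD10 by 1.00 ± 0.21 (adjusted p = 0.0299). With cycloheximide itself ERD14 (0.39), CBF2 (0.73) and ERD10 (0.67) were not called (adjusted p = 0.296, 0.103 and 0.329). At 4 h ERD14 and ERD10 were called lower (-0.72 and -0.58), so part of their difference lay in the time course. None of these is among the 23 genes called with each experiment's own spread.

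At 12 h neighbouring genes were often called in the same direction, among them IAA3 (0.89) with AXR3 (1.16), GA20OX1 (2.71) with TRM23 (0.78), and CYP706A3 (-1.17) with AT5G44630 (-1.61). Of adjacent pairs among 23545 placed genes, 396 were called in the same direction, against a median of 217 and a highest of 268 in 1000 random placements of the calls (permutation p = 0.001, the smallest these can give), and 123 in opposite directions. Neighbours may respond together, but related tandem copies whose probes read each other's RNA were not separated from the rest, so that explanation stays open.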
